A study of Homo sapiens with 17 samples.

How the data were processed

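RNA was measured in 17 libraries from formalin-fixed, paraffin-embedded human brain tissue, 13 from primary central nervous system vasculitis and 4 from normal brain, prepared per the labels with a TruSeq Stranded Total RNA access kit. The authors deposited 1 table of raw counts per gene, with no normalization, and the processing notes name FastQC, STAR (2.6.1c) and Subread and the build hg38. The table also gives each gene's start, end and length, which per the file headers are coordinates in bases (other than a measurement). The notes give no parameters, no annotation release and no strand setting for the counting, so reads of overlapping antisense genes and of paralogs (HLA, immunoglobulin, globin, chemokine and complement genes) are only as separate as the deposited counts make them.

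The 17 count columns were matched to the samples by the codes in the titles, and no sample column was left unused. No pair of columns was identical. The table lists 64253 genes. The 4146 entries off the primary chromosomes and the 617 entries that are Y-linked, XIST or TSIX were left out of all tests. Totals ran from 2.58 to 126.7 M counts, and no batch, date or donor is labelled. The codes of all normal libraries, and of no PCNSV library, end in _R, a mark that the labels do not explain. Replicate libraries correlated (Spearman, across genes, which are not independent replicates) at 0.781 to 0.897 in AB, 0.532 to 0.886 in GV, 0.468 to 0.902 in LV and 0.725 to 0.921 in normal brain.

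Genes were filtered with filterByExpr (minimum count 10, by diagnosis), scaled by TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The diagnosis was the only term when PCNSV was compared with normal brain. The codes were compared in a fit with 4 groups. SE of a log2 fold change is its size divided by the square root of F. CPM used TMM-scaled totals. Normal and PCNSV replicate numbers do not pair the samples. The common biological coefficient of variation was 1.02.

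A set of 40 gene lists with 639 symbols was written before the data were examined: T cell, CD8 and NK cytotoxic, B cell, plasma cell and immunoglobulin, monocyte and macrophage, granuloma and lipid-laden macrophage, microglia, neutrophil, dendritic cell, endothelial, smooth muscle and pericyte, fibroblast and meningeal, excitatory neuron, inhibitory neuron, synaptic, cerebellar neuron, astrocyte, reactive astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, red cell, type I interferon, interferon gamma, MHC class II, MHC class I, complement, chemokines, cytokines, toll-like receptor and inflammasome, co-stimulation and checkpoint, leukocyte adhesion, matrix remodelling, amyloid precursor processing and clearance, hypoxia, proliferation, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, immediate early, heat shock, and ribosomal protein. Lists with at least 4 tested members were tested with camera of edgeR and limma (3.58.1; preset correlation 0.01, two-sided), adjusted over all lists of a comparison. The list level of a library is the mean log2 CPM of the tested members with a prior count of 2. Levels were compared by exact two-sided permutation of the 13 and 4 library labels (2380 splits, smallest possible p 0.00042), adjusted over the 40 lists, a test added after the estimated correlations were seen.

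Named genes followed a rule also written before the data were examined. It took the 12 largest rises and the 12 largest falls among genes called between PCNSV and normal brain with a mean log2 CPM of at least 2, a plain gene symbol and every PCNSV library beyond the normal median. It also took from each list up to 4 tested members with the smallest p, and from each comparison of codes the largest called changes, of which there were none. The text gives the examples among them that its groups call for. A gene with no count in normal brain is given as a lower bound against a floor of 3 counts per normal library. A gene with 1 to 3 counts is given as the ratio of summed counts scaled by depth, with a 95% counting interval. Intervals and floors cover counting error only, and reads without molecular identifiers include copies made by PCR.

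The method was tested on simulated data made from the spread of these libraries. Each size and direction of change was planted in 25 genes with a mean log2 CPM over 2, in a single simulated set per planted group. Genes were drawn independently, so these rates do not cover genes of lower counts or genes that vary together. Of planted 16-fold changes between 13 and 4 libraries, 88% to 92% were called, of 4-fold changes 28% to 36%, and of 2-fold changes 8% to 12%. Of 20516 unchanged genes 6 were called. In 20 simulated sets the planted T cell list was called in 18, complement in 20 and ribosomal proteins in 20, and 3 of 740 tests of unplanted lists were called. On the real libraries this rate was far higher: other splits into 13 and 4 called a median of 13 of 40 lists. A planted trend on length and GC content correlated with the estimated log2 fold changes at 0.687, and at 0.0213 after removal.

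Alternatives planned before the data were examined were relative log expression and upper-quartile scaling, no filter and a filter of 1 CPM in 4 libraries, DESeq2 (1.42.0), limma-voom with quality weights, the total count as a covariate, a 4-group fit, the replicate number as a block, fits of the 2 compared codes alone, an estimated correlation for camera, and leaving out each library in turn. Added after the data were seen were the removal of each library's trend on gene length and GC content, the number of genes at 2.5 M counts and the excitatory neuron level as covariates, genes with a mean log2 CPM of at least 4 only, and leaving out the 3 libraries under 10 M counts. Also added were leaving out the 3 PCNSV libraries lowest in synaptic genes and the permutation of list levels without each library. The replicate block compares AB libraries alone with normal brain, since no normal library shares a number with a GV or LV library. These numbers do not pair the samples, and some of the highest adjusted p over the alternatives come from that fit. GC content came from GENCODE transcripts, the longest per gene, and was known for 98.5% of the tested genes.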

Results

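Gene expression was measured by RNA sequencing in formalin-fixed, paraffin-embedded human brain biopsies, 13 from primary central nervous system vasculitis (PCNSV, an inflammation of vessels restricted to brain and spinal cord) and 4 of normal brain. The labels give this preparation for all 17 samples, and do not say where the normal tissue came from. The PCNSV libraries carry 1 of 3 letter codes whose meaning the labels do not give: AB (n = 4, replicates 1 to 4), GV (n = 4, replicates 5 to 8) and LV (n = 5, replicates 9 to 13). Total counts of the AB libraries were 24.7, 65.8, 36.5 and 8.66 M, and those of the GV libraries 35.4, 41.5, 33.9 and 42.6 M. The LV libraries held 2.58, 33.3, 55.1, 59.2 and 91.4 M, and the normal libraries 88.7, 7.01, 126.7 and 42.2 M. Thinned to 2.5 M counts each, PCNSV libraries showed 18162 ± 1630 genes (SD, n = 13) and normal libraries 15774 ± 2265 (SD, n = 4). MALAT1, a nuclear noncoding RNA, took 7.52% ± 2.42 of the counts in PCNSV (SD, n = 13) and 1.52% ± 0.614 in normal brain (SD, n = 4). Nothing beyond the labels says which donors the libraries came from, so the p of single genes and of permutations measures the spread between samples. The p of camera instead weighs a list's genes against all other genes, with the correlation between genes preset or estimated.

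**Figure D1:**
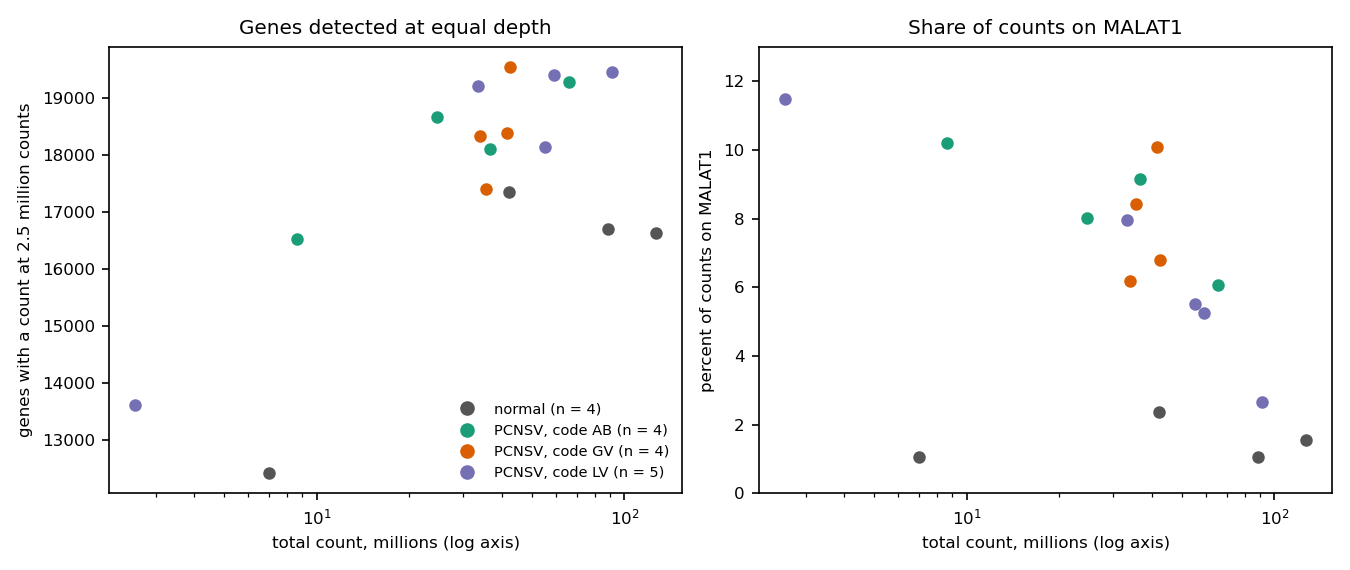
Genes with a count after thinning each library to 2.5 M counts (left) and MALAT1 as a percent of all counts (right), both against the total count in M on a log axis, 1 point per library and colours by group. MALAT1 lies between 2.66% and 11.5% in the 13 PCNSV libraries and between 1.06% and 2.37% in the 4 normal libraries.

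The comparison of PCNSV with normal brain asks how gene expression in the diseased biopsies differs from that of control tissue, the purpose the labels give. Lists of innate sensing, MHC class II, T cell and plasma cell genes were higher in PCNSV by an exact permutation of list levels, and lists of ribosomal, respiratory chain and heat shock genes were lower. Their calls by a competitive test (camera) ended with an estimated correlation (adjusted p = 0.614 for the higher lists and the ribosomal and mitochondrial lists, 0.598 and 0.239 for the nuclear-encoded respiratory chain and heat shock lists, each with an estimated correlation). NLRP3, the sensor of an inflammasome, averaged 36.2 ± 25.6 CPM (SD, n = 13) against 0.788 ± 0.646 (SD, n = 4), a 42.6-fold rise. HSP90AA1, an abundant chaperone, averaged 1030 ± 317 CPM against 3823 ± 430, a log2 fold change of -1.89 ± 0.22 (SE). Of 20716 genes tested, 2130 were higher and 1645 lower in PCNSV (18.2%), and 2030 and 1370 of them differed at least 2-fold. With trends on gene length and GC content removed the balance turned, to 1611 higher and 2619 lower. DESeq2 called 4607 higher and 1681 lower, limma-voom 3078 and 2831, and a covariate for genes at thinned depth left 1349 and 1404. Among the higher genes, 537 (25.2%) had no count in any normal library. Among the 8951 genes with a mean log2 CPM of at least 4, 1025 were higher and 1438 lower. Every PCNSV library lay above the normal median for 1096 of the higher genes, and below it for 1494 of the lower genes. The calls rest on few controls: without normal replicate 1 they numbered 1054 and 1077, without normal replicate 3 1029 and 903, and without normal replicate 2 1387 higher. Without the 3 PCNSV libraries lowest in synaptic genes they numbered 1945 and 1593.

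Some genes that sense microbes and danger signals rose in PCNSV. NLRP3 (ENSG00000162711, hg38 chromosome 1, 247416156 to 247449108) changed by 5.41 ± 0.91 on the log2 scale (SE; adjusted p = 0.000551) and was higher than the normal median in 13 of 13 PCNSV libraries. It was 1 of 4 toll-like receptor and inflammasome genes that rose of 17 tested (6 adjusted over the list alone). TLR6, a receptor for bacterial lipopeptides, rose by 2.89 ± 0.77 (adjusted p = 0.0144), or 3.69 without normal replicate 3. TLR2, its partner, rose by 2.92 ± 0.88 (adjusted p = 0.0267), a call that ended without normal replicate 1, 2 or 3 (adjusted p = 0.0857, 0.0859 and 0.0893), while its change was 4.06 without normal replicate 4. The remaining 1 was TLR4, the endotoxin receptor, at 1.06 ± 0.34, whose call ended without AB replicate 1 (adjusted p = 0.0504) or normal replicate 1, 2 or 4 (0.0642, 0.104 and 0.112). TLR2 passed in 26 of 32 alternatives (adjusted p of 0.000245 to 0.137) and TLR4 in 22 of 32 (0.00201 to 0.292). Over the alternatives the log2 fold change of TLR2 ran from 1.96 to 4.06. The list's level, the mean log2 CPM of its members, was 2.90 ± 1.26 in PCNSV (SD, n = 13) and 0.18 ± 1.64 in normal brain (SD, n = 4), with an adjusted exact permutation p = 0.0216. Its competitive test (camera) gave adjusted p = 0.000682, and adjusted p = 0.614 with an estimated correlation. Leaving out normal replicate 1, 2 or 3 changed the adjusted exact permutation p to 0.0536, 0.111 and 0.0714.

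Some genes of antigen presentation by MHC class II also rose. HLA-DQA1 (ENSG00000196735, chromosome 6, 32628179 to 32647062), a chain that presents peptides to helper T cells, averaged 78.4 ± 88.8 CPM (SD, n = 13) against 2.14 ± 1.96 (SD, n = 4), a log2 fold change of 5.13 ± 1.14 (SE; adjusted p = 0.0051). Reads of HLA genes are partly shared between them, and the call ended under limma-voom (adjusted p = 0.0779; alternatives 1.88e-09 to 0.337). Of 14 class II genes, 5 rose (11 adjusted over the list alone), and the list's level differed by 3.01 between PCNSV and normal brain (adjusted exact permutation p = 0.0216; camera adjusted p = 0.00156, and adjusted p = 0.614 with an estimated correlation). That adjusted exact permutation p was 0.0536, 0.107 and 0.0714 without normal replicate 1, 2 or 3. Among the class I presentation genes 3 of 15 rose (3 adjusted over the list alone), and the level was 5.82 ± 1.26 in PCNSV and 4.31 ± 1.04 in normal brain (adjusted exact permutation p = 0.0791). One of them was NLRC5, a transactivator of class I genes, at 3.96 ± 1.16, whose call ended without normal replicate 1 or 3 (adjusted p = 0.0807 and 0.0721). It passed in 26 of 32 alternatives (2.2e-05 to 0.122). The type I interferon response had 3 of 18 genes higher (4 adjusted over the list alone), among them OAS2, a sensor of double-stranded RNA, at 3.99 ± 1.13 (adjusted p = 0.0197), a call that ended with genes at thinned depth as covariate (adjusted p = 0.133; alternatives 4.34e-06 to 0.312). Its level differed by 1.89 (adjusted exact permutation p = 0.0373; camera adjusted p = 0.0329, and adjusted p = 0.614 with an estimated correlation). The permutation call ended without the 3 libraries lowest in synaptic genes (0.0633) and without normal replicate 1, 2 or 3 (0.0635, 0.148 and 0.0714), and the camera call without GV replicate 6, LV replicate 11 or normal replicate 4 (0.0553, 0.0548 and 0.0606). Of 15 interferon gamma response genes 3 rose (3 adjusted over the list alone). They included GBP5, an interferon-induced GTPase, at 9.17 ± 2.01, or 8.58 without GV replicate 6. Without normal replicate 1 a single normal count was left, a ratio of 9131 scaled by depth with a 95% counting interval of 1639 to 360681. That list's level differed by 2.72 (adjusted exact permutation p = 0.0584). Over the alternatives the log2 fold changes ran from 3.77 to 5.80 for HLA-DQA1, 2.28 to 4.62 for NLRC5 and 2.51 to 4.97 for OAS2.

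Some myeloid genes rose. Of all 20716 tested genes 2130 were called higher. The called shares of the monocyte and macrophage, microglia and complement lists were close to that. ITGAX (ENSG00000140678, chromosome 16, 31355134 to 31382997), the CD11c integrin of dendritic cells and macrophages, averaged 208 ± 248 CPM (SD, n = 13) against 12.3 ± 8.26 (SD, n = 4), a log2 fold change of 4.08 ± 0.99 (SE; adjusted p = 0.00881). It was 1 of 3 leukocyte adhesion genes that rose of 14 tested (3 adjusted over the list alone; level difference 1.91, adjusted exact permutation p = 0.0525). C2 (ENSG00000166278, chromosome 6, 31897785 to 31945672), a protease of the classical complement pathway, averaged 51.1 ± 44.2 CPM against 4.05 ± 3.57, a change of 3.63 ± 0.91 (adjusted p = 0.0101). The other complement gene called of 17 was C3, the central component, at 913 ± 704 CPM against 228 ± 197. Its call ended without LV replicate 12 (adjusted p = 0.0504) or normal replicate 1, 2 or 3 (0.12, 0.113 and 0.121), its log2 fold change was 2.84 without normal replicate 4, and it passed in 21 of 32 alternatives (0.00185 to 0.161). Complement had 1 call adjusted over the list alone, and its level differed by 1.53 (adjusted exact permutation p = 0.0525). In the microglia list 1 of 11 genes rose (1 adjusted over the list alone), OLFML3, a secreted glycoprotein, by 3.50 ± 0.92 (adjusted p = 0.0127; above the normal median in 12 of 13 libraries). The microglia level differed by 2.34 (adjusted exact permutation p = 0.0216; camera adjusted p = 0.0158, and adjusted p = 0.614 with an estimated correlation), with adjusted exact permutation p of 0.0536, 0.117 and 0.0714 without normal replicate 1, 2 or 3. Monocyte and macrophage genes rose in 2 of 20 cases (2 adjusted over the list alone; level difference 2.30, adjusted exact permutation p = 0.0672), granuloma and lipid-laden macrophage genes in 4 of 14 (5 adjusted over the list alone; 2.02, adjusted exact permutation p = 0.0542). CHIT1, a chitinase of activated macrophages, was among the latter, with 13146 counts in PCNSV and 1 in normal brain. The ratio of its counts scaled by depth was 5615, with a 95% counting interval of 1008 to 221780. Without normal replicate 1, which held that count, it was at least 132-fold higher, and without normal replicate 3 the ratio was 3080 (553 to 121661). The log2 fold changes ran, over the alternatives, from 2.74 to 4.52 for ITGAX, 2.72 to 4.21 for C2, 1.16 to 2.84 for C3 and 2.84 to 3.85 for OLFML3. None of 10 neutrophil genes was called (0 adjusted over the list alone; level difference 0.44, adjusted exact permutation p = 0.688).

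Many lymphocyte genes had no count in normal brain: 5 of 17 T cell and 8 of 17 plasma cell and immunoglobulin genes. T cell genes rose in 8 of 17 cases (12 adjusted over the list alone), and the list's level was 0.74 ± 2.57 in PCNSV (SD, n = 13) and -3.13 ± 0.36 in normal brain (SD, n = 4; adjusted exact permutation p = 0.0382; camera adjusted p = 0.000682, and adjusted p = 0.614 with an estimated correlation). The T cell permutation call ended without LV replicate 11 (0.0519) or normal replicate 1, 2, 3 or 4 (0.0714, 0.107, 0.0714 and 0.0536). Plasma cell and immunoglobulin genes rose in 11 of 17 cases (12 adjusted over the list alone), with a level difference of 4.62 (adjusted exact permutation p = 0.0216; camera adjusted p = 0.000682, and adjusted p = 0.614 with an estimated correlation). That adjusted permutation p was 0.0536, 0.0714 and 0.0714 without normal replicate 1, 2 or 3. Against a floor of 3 counts per normal library, which averages 0.153 CPM, IGHG2 and IGLC2, immunoglobulin constant regions, were at least 325-fold and at least 930-fold higher. CD3D, a chain of the T cell receptor complex, was at least 84.4-fold higher, SKAP1, a T cell adaptor, at least 16.9-fold, and CTLA4, an inhibitory receptor, at least 22.3-fold. The bound of IGLC2 was 598 without LV replicate 9. Without normal replicate 2 the floor was 0.0459 CPM, which raises the bounds to 1087, 3108, 282, 56.5 and 74.4. The calls of CD3D and CTLA4 ended without normal replicate 3 (adjusted p = 0.0545 and 0.0543). Under limma-voom the calls of IGHG2, IGLC2, CD3D and CTLA4 ended (adjusted p = 0.0956, 0.118, 0.0727 and 0.0612). Over all alternatives their adjusted p reached 0.0956, 0.118, 0.0759 and 0.213 and that of SKAP1 0.342, the smallest being 2.05e-12. The synaptic level of GV replicates 5 and 6 and LV replicate 11 was 1.48 to 2.23, and their T cell level was 3.17 to 4.42, against -3.17 to 3.36 in the other 10 PCNSV libraries. Without these 3 libraries the T cell level difference was 2.95 (adjusted exact permutation p = 0.0633), and the bounds of IGHG2, IGLC2, CD3D, SKAP1 and CTLA4 were 263, 764, 40.6, 8.60 and 9.90.

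Other lists of lymphoid cells and their signals follow. B cell genes rose in 2 of 10 cases (6 adjusted over the list alone): MS4A1, which encodes CD20, and BLK, a B cell kinase. Both calls ended without normal replicate 1 (adjusted p = 0.0663 and 0.0681) or normal replicate 3 (0.0728 and 0.0747). MS4A1 passed in 26 of 31 alternatives (4.73e-05 to 0.207) and BLK in 27 of 31 (7.17e-05 to 0.303). The B cell level differed by 1.35 (adjusted exact permutation p = 0.0465; camera adjusted p = 0.282, and adjusted p = 0.614 with an estimated correlation). That call ended without AB replicate 1 (0.0537), AB replicate 2 (0.0558), GV replicate 5 (0.0612), GV replicate 6 (0.0517), LV replicate 10 (0.0508), LV replicate 11 (0.0642) and LV replicate 12 (0.0642). It also ended without normal replicate 1 (0.0918), 2 (0.107), 3 (0.0873) or 4 (0.0714), and without the 3 libraries lowest in synaptic genes (0.0999). Dendritic cell genes rose in 4 of 11 cases (8 adjusted over the list alone), among them IRF8, a transcription factor of dendritic cells, at 4.13 ± 1.15, whose call ended without normal replicate 1 or 3 (adjusted p = 0.0643 and 0.0601) and whose change was 5.77 without normal replicate 4. The dendritic cell level differed by 2.58 (adjusted exact permutation p = 0.0273; camera adjusted p = 0.0303, and adjusted p = 0.614 with an estimated correlation). The adjusted permutation p was 0.0633 without the 3 libraries lowest in synaptic genes and 0.0536, 0.117 and 0.0714 without normal replicate 1, 2 or 3. The adjusted camera p was 0.0517 without normal replicate 3. Cytotoxic CD8 and NK genes rose in 5 of 16 cases (8 adjusted over the list alone; level difference 2.21, adjusted exact permutation p = 0.0588). Of 15 co-stimulation and checkpoint genes 5 rose (6 adjusted over the list alone; 2.42, adjusted exact permutation p = 0.0542), with HAVCR2, which encodes TIM-3, at 3.51 ± 0.86 (adjusted p = 0.00836; 4.19 without normal replicate 4). Chemokine genes rose in 2 of 16 cases (1 adjusted over the list alone; 1.64, adjusted exact permutation p = 0.102). One was CCL4, a chemoattractant of monocytes and T cells whose reads are partly shared with paralogs, at 78.3 ± 174 CPM with no count in normal brain, at least 511-fold higher. Its bound was 203 without GV replicate 6, 116 without the 3 libraries lowest in synaptic genes, and 1706 without normal replicate 2. The CCL4 call ended under limma-voom (adjusted p = 0.0613; alternatives 6.45e-14 to 0.0613). Over the alternatives the log2 fold changes ran from 3.22 to 5.77 for IRF8 and 2.66 to 4.19 for HAVCR2. Cytokine genes rose in 2 of 18 cases (0 adjusted over the list alone; 1.93, adjusted exact permutation p = 0.0741). The called shares of the chemokine and cytokine lists were close to that of all tested genes, 2130 higher of 20716. Proliferation genes rose in 3 of 14 (3 adjusted over the list alone; 2.10, adjusted exact permutation p = 0.0767).

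**Figure D2:**
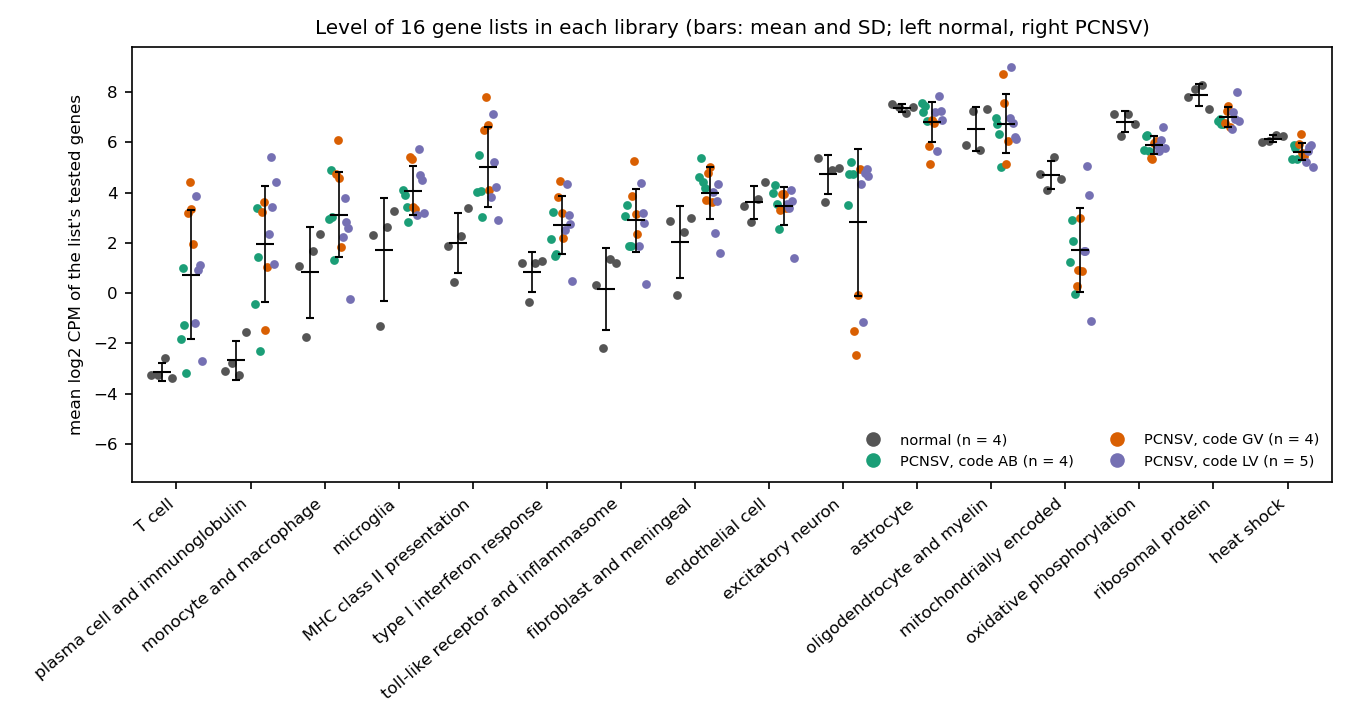
Mean log2 CPM of the members of 16 gene lists in each library, with all lists along a shared axis. For each list normal libraries lie left and PCNSV libraries right, with points coloured by group. Bars give the mean and SD of the normal libraries and of all PCNSV libraries. The T cell level runs from -3.17 to 4.42 in the 13 PCNSV libraries and from -3.37 to -2.59 in the 4 normal libraries.

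Stromal and vascular genes went both ways. FBN1 (ENSG00000166147, chromosome 15, 48408306 to 48645849), fibrillin of extracellular microfibrils, averaged 434 ± 144 CPM (SD, n = 13) against 102 ± 44.7 (SD, n = 4), a log2 fold change of 2.09 ± 0.37 (SE; adjusted p = 0.000885). Fibroblast and meningeal genes rose in 5 of 16 cases (7 adjusted over the list alone), FBN1 and 4 collagens, such as COL1A1 at 4.96 ± 1.38, whose call ended without normal replicate 1 or 3 (adjusted p = 0.0681 and 0.0723) and whose change was 6.45 without normal replicate 4. The COL1A1 call also ended under limma-voom (adjusted p = 0.0658; alternatives 1.36e-06 to 0.125). The list's level differed by 1.94 (adjusted exact permutation p = 0.0382; camera adjusted p = 0.0363, and adjusted p = 0.614 with an estimated correlation). The permutation call ended without AB replicate 1 (0.0537), the 3 libraries lowest in synaptic genes (0.0599) or normal replicate 1, 2 or 3 (0.0643, 0.155 and 0.0714), and the camera call without AB replicate 2 or 3 (0.0553 and 0.051) or normal replicate 2 or 3 (0.0524 and 0.0643). Camera also lost it with trends on gene length and GC content removed (0.0756), where the list's median fell from 2.27 to 1.58. The same happened with genes at thinned depth (0.0931) or the neuron level (0.059) as covariate, and among genes with a mean log2 CPM of at least 4 (0.0561). RGS5, a pericyte marker, was the 1 of 13 smooth muscle and pericyte genes that fell (1 adjusted over the list alone), from 56.4 ± 20.5 to 16.4 ± 9.58 CPM, a change of -1.78 ± 0.44 (adjusted p = 0.0093). That list's median log2 fold change was -0.10, and 0.06 under relative log expression scaling (level difference -0.53, adjusted exact permutation p = 0.484). Endothelial genes fell in 2 of 15 cases (3 adjusted over the list alone): FLT1, a VEGF receptor, and SLC2A1, the glucose transporter of brain capillaries. FLT1 changed by -1.77 ± 0.47, or -0.74 without normal replicate 2 (adjusted p = 0.282), and passed in 27 of 32 alternatives (0.00116 to 0.362). SLC2A1 changed by -1.03 ± 0.35 and passed in 11 of 32 (0.00714 to 0.426). Its call ended without AB replicate 1, 2, 3 or 4 (0.0524, 0.0617, 0.0528 and 0.0525), GV replicate 5, 6, 7 or 8 (0.0568, 0.0577, 0.0526 and 0.0645), LV replicate 10 or 13 (0.061 and 0.0517), or normal replicate 2, 3 or 4 (0.0591, 0.0834 and 0.275). The endothelial median was -0.04, 0.11 under relative log expression scaling and -0.85 with trends on length and GC content removed (level difference -0.14, adjusted exact permutation p = 0.791). Matrix remodelling genes had 1 rise and 1 fall among 17 (1 and 1 adjusted over the list alone; level difference 1.42, adjusted exact permutation p = 0.158). The rise was PLAU, urokinase, at 7.16 ± 1.80, or 6.37 without GV replicate 6 and 7.99 without normal replicate 4. Hypoxia genes had 2 rises and 2 falls among 13 (2 and 2 adjusted over the list alone), with a median of -0.06, and 0.08 under relative log expression scaling (level difference 0.03, adjusted exact permutation p = 0.928). Of 8 red cell genes 1 fell (0 adjusted over the list alone; level difference -1.92, adjusted exact permutation p = 0.262), HBA1, an alpha globin whose reads are shared with its copy. Its change of -3.18 ± 1.03 was -1.34 without normal replicate 2 (adjusted p = 0.451), and it passed in 14 of 32 alternatives (0.00243 to 0.597). The HBA1 call further ended without AB replicate 2, 3 or 4 (0.0536, 0.0524 and 0.0506), GV replicate 5 or 8 (0.0543 and 0.0606), LV replicate 10, 12 or 13 (0.0501, 0.0551 and 0.0584), or normal replicate 3 (0.0722). The log2 fold changes ran, over the alternatives, from 1.501 to 2.34 for FBN1, 3.88 to 6.45 for COL1A1, 5.39 to 7.99 for PLAU, -2.55 to -0.44 for FLT1, -1.77 to -0.59 for SLC2A1 and -5.01 to -1.12 for HBA1.

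**Figure D3:**
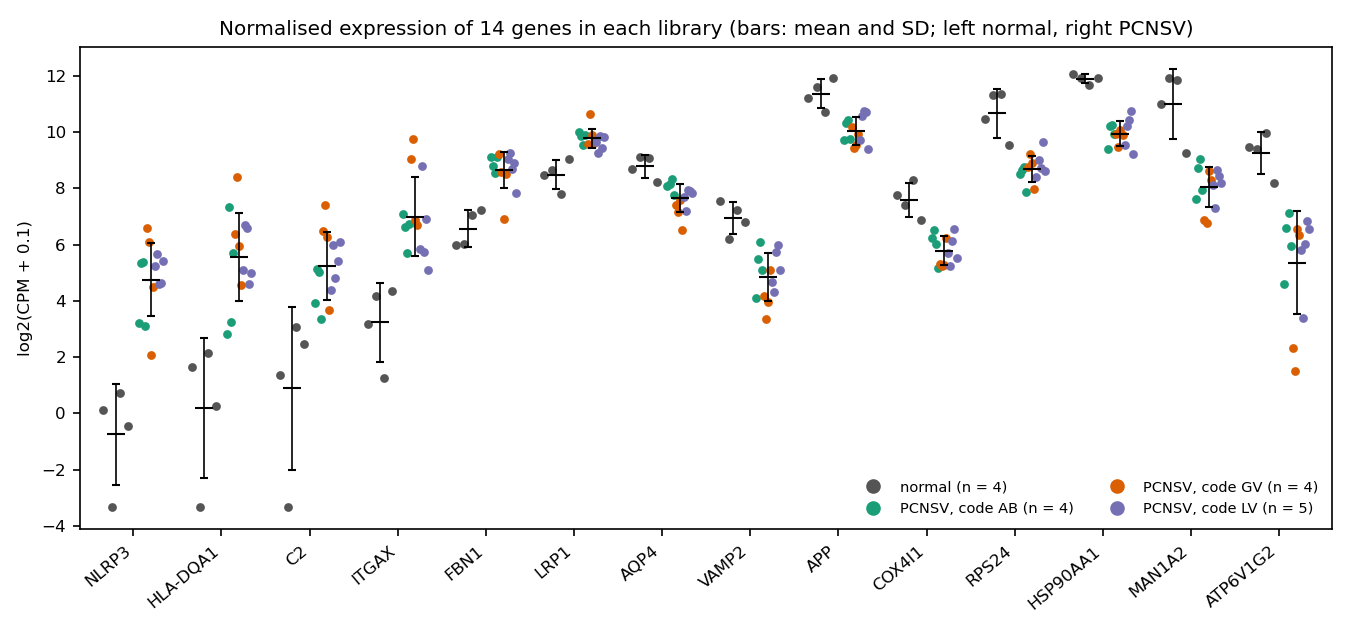
log2 of CPM plus 0.1 of 14 genes in each library, with all genes along a shared axis. For each gene normal libraries lie left and PCNSV libraries right, with points coloured by group. Bars give the mean and SD of the normal libraries and of all PCNSV libraries. NLRP3 averages 36.2 CPM in PCNSV and 0.788 in normal brain, and HSP90AA1 averages 1030 and 3823.

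Neuronal, synaptic and astrocyte lists did not pass the exact permutation of list levels, while single synaptic and astrocyte genes fell. VAMP2 (ENSG00000220205, chromosome 17, 8159149 to 8163546), a vesicle fusion protein of synapses, averaged 33.7 ± 19 CPM (SD, n = 13) against 130 ± 48.2 (SD, n = 4), a log2 fold change of -1.95 ± 0.39 (SE; adjusted p = 0.00205). Of 20 synaptic genes 2 fell and 1 rose (2 and 1 adjusted over the list alone), with a level difference of -1.49 (adjusted exact permutation p = 0.262). The rise was SHANK3, a scaffold of postsynaptic sites, at 2.22 ± 0.54 (adjusted p = 0.00844), or 2.81 without normal replicate 4 and 1.01 with trends on gene length and GC content removed. No gene was called among 12 excitatory and 14 inhibitory neuron genes (0 and 0 adjusted over the list alone; level differences -1.90 and -1.17, adjusted exact permutation p = 0.355 and 0.407). Cerebellar neuron genes had 1 rise among 10 (0 adjusted over the list alone; 0.58, adjusted exact permutation p = 0.682). This was CBLN3, a granule cell gene, with 43.1 CPM in GV replicate 7 and at most 4.13 in the other PCNSV libraries. Its 1972 counts in PCNSV and 3 in normal brain give a ratio of 281 scaled by depth, with a 95% counting interval of 95.9 to 1363. The ratio was 58.4 (19.8 to 285) without GV replicate 7, 183 (62.7 to 890) without normal replicate 1 and 462 (82.8 to 18258) without normal replicate 3. Its call ended without any 1 normal library (adjusted p = 0.0999, 0.0806, 0.0968 and 0.0657 for normal replicates 1 to 4), and passed in 22 of 30 alternatives (0.000888 to 0.689). AQP4 (ENSG00000171885, chromosome 18, 26852038 to 26865818), the water channel of astrocyte endfeet, fell from 451 ± 121 to 212 ± 64.1 CPM, a change of -1.09 ± 0.25 (adjusted p = 0.00635; below the normal median in 13 of 13 libraries). With genes at thinned depth as covariate the AQP4 call ended (adjusted p = 0.0509; alternatives 0.00249 to 0.212). Astrocyte genes had 2 falls and 1 rise among 14 (4 and 1 adjusted over the list alone; level difference -0.57, adjusted exact permutation p = 0.256). No gene was called among 12 reactive astrocyte, 14 oligodendrocyte and myelin, and 12 oligodendrocyte precursor genes (0 adjusted over the list alone in each). Their level differences were -0.54, 0.20 and 0.51 (adjusted exact permutation p = 0.489, 0.791 and 0.262). The median of the reactive astrocyte list was -0.16, and 0.00 under relative log expression scaling, and that of the precursor list 0.06, and -0.43 with trends on gene length and GC content removed. The oligodendrocyte list had a median log2 fold change of 0.46 and a mean of 0.43, while its camera test pointed down (adjusted p = 0.995). GV replicates 5 and 6 and LV replicate 11 held synaptic levels of 1.48 to 2.23, against 6.31 to 7.57 in the other 10 PCNSV libraries and 6.39 to 7.84 in normal brain, and myelin levels of 7.56 to 8.99. Their astrocyte levels were 5.15 to 5.85, against 6.76 to 7.86 in the other PCNSV libraries and 7.16 to 7.54 in normal brain.

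**Figure D4:**
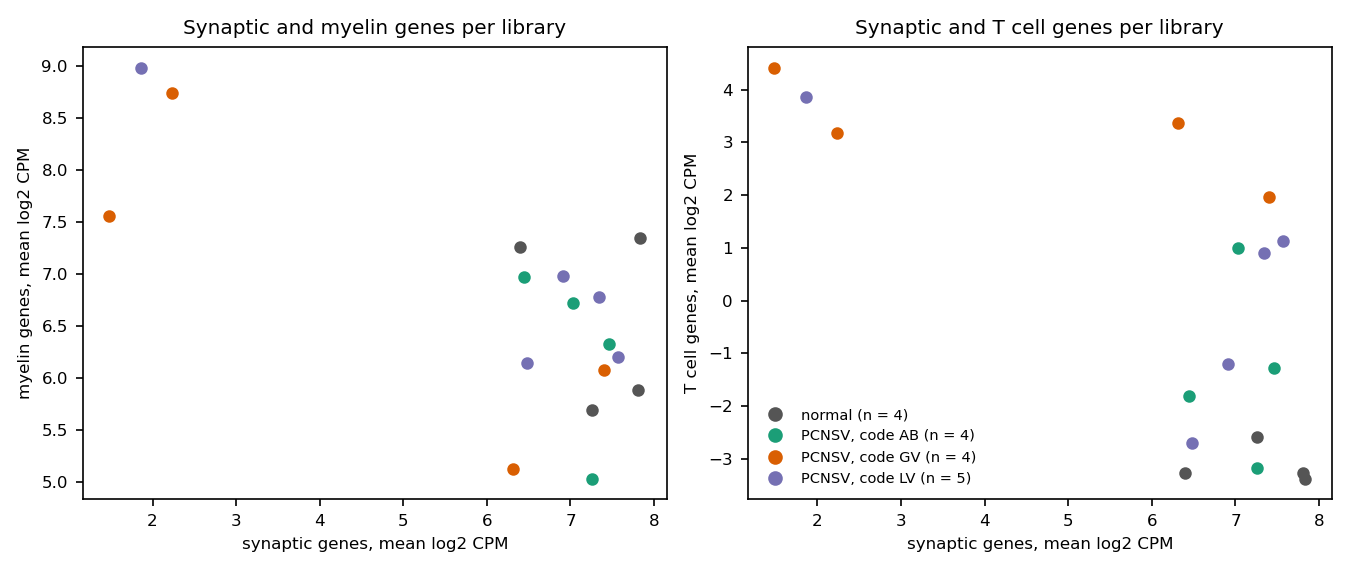
Level of the synaptic list against that of the oligodendrocyte and myelin list (left) and of the T cell list (right), all as mean log2 CPM, 1 point per library and colours by group. The 3 PCNSV libraries with synaptic levels of 1.48 to 2.23 have myelin levels of 7.56 to 8.99 and T cell levels of 3.17 to 4.42.

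Some genes of protein synthesis and respiration fell. RPS24 (ENSG00000138326, chromosome 10, 78033760 to 78056812), a protein of the small ribosomal subunit, averaged 435 ± 146 CPM (SD, n = 13) against 1818 ± 909 (SD, n = 4), a log2 fold change of -2.06 ± 0.28 (SE; adjusted p = 8.15e-05). Ribosomal protein genes fell in 12 of 22 cases (13 adjusted over the list alone), with a level difference of -0.89 (adjusted exact permutation p = 0.0216; camera adjusted p = 1.9e-08, and adjusted p = 0.614 with an estimated correlation). COX4I1 (ENSG00000131143, chromosome 16, 85798633 to 85807044), a subunit of cytochrome c oxidase, averaged 58.4 ± 21.3 CPM against 203 ± 82.8, a change of -1.80 ± 0.29 (adjusted p = 0.00033). COX6C, another subunit, changed by -2.45 ± 0.41. Nuclear-encoded respiratory chain genes fell in 12 of 21 cases (13 adjusted over the list alone; level difference -0.94, adjusted exact permutation p = 0.0216; camera adjusted p = 4.54e-08, and adjusted p = 0.598 with an estimated correlation). Of 13 mitochondrially encoded genes 6 fell (9 adjusted over the list alone), with a level difference of -2.97 (adjusted exact permutation p = 0.0216; camera adjusted p = 4.68e-08, and adjusted p = 0.614 with an estimated correlation). MT-ND3, a subunit of complex I, changed by -3.12 ± 0.71 (adjusted p = 0.00525). Without normal replicate 1, 2 or 3 the adjusted exact permutation p was 0.0536, 0.107 and 0.0714 for the ribosomal list, 0.0536, 0.0714 and 0.0714 for the nuclear-encoded list, and 0.0536, 0.0952 and 0.0714 for the mitochondrial list. MALAT1 took 2.66% to 11.5% of the counts in the PCNSV libraries and 1.06% to 2.37% in the normal libraries. The mitochondrial call also ended without the 3 libraries lowest in synaptic genes (0.0633), and over the alternatives the change of MT-ND3 ran from -4.86 to -2.59.

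Heat shock genes fell in 5 of 12 cases and rose in 1 (7 and 1 adjusted over the list alone). HSP90AA1 (ENSG00000080824, chromosome 14, 102080738 to 102139699; adjusted p = 3.13e-05) and HSPA8, the constitutive HSP70 chaperone, at -1.21 ± 0.24 (adjusted p = 0.00178), lay below the normal median in 13 of 13 PCNSV libraries. HSPA6, a strictly inducible HSP70, rose, with 2257 counts in PCNSV and 2 in normal brain, a ratio of 482 scaled by depth with a 95% counting interval of 133 to 3982. The HSPA6 call ended without normal replicate 3 (adjusted p = 0.0525), where the ratio was 264 (73.1 to 2185), against 315 (87.1 to 2602) without normal replicate 1. It was at least 21.8-fold higher without normal replicate 4, which held the normal counts. The list's level differed by -0.51 (adjusted exact permutation p = 0.0448; camera adjusted p = 0.000682, and adjusted p = 0.239 with an estimated correlation). The permutation call ended without AB replicate 1 (0.0537), AB replicate 2 (0.0513), GV replicate 7 (0.0609), GV replicate 8 (0.0612), LV replicate 10 (0.0508), LV replicate 11 (0.0623) and LV replicate 12 (0.0513). It also ended without normal replicate 1 (0.0714), 2 (0.107), 3 (0.0977) or 4 (0.068). Immediate early genes rose in 2 of 15 cases (6 adjusted over the list alone; level difference 2.15, adjusted exact permutation p = 0.0525). EGR2, a transcription factor of early responses, averaged 68.4 ± 111 CPM (SD, n = 13) against 0.0123 ± 0.0245 (SD, n = 4). Its change of 11.77 ± 2.32 (SE; adjusted p = 0.00242) was 11.15 without GV replicate 6 and 11.14 without normal replicate 3. It was at least 356-fold higher without normal replicate 1, which held its normal counts. IER2, the other one, rose by 3.79 ± 1.12, and its call ended without normal replicate 1, 2 or 4 (adjusted p = 0.0752, 0.0565 and 0.0611). It was 5.06 without normal replicate 3, and passed in 24 of 31 alternatives (1.38e-05 to 0.369). Over the alternatives the log2 fold change of IER2 ran from 2.997 to 5.06.

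Genes of amyloid precursor processing and clearance had 2 rises and 3 falls among 17 (2 and 3 adjusted over the list alone; level difference 0.24, adjusted exact permutation p = 0.277). APP (ENSG00000142192, chromosome 21, 25880550 to 26171128), the amyloid precursor itself, averaged 1102 ± 373 CPM (SD, n = 13) against 2763 ± 952 (SD, n = 4), a log2 fold change of -1.33 ± 0.26 (SE; adjusted p = 0.0016). CLU, an extracellular chaperone that binds amyloid, changed by -0.98 ± 0.24 (adjusted p = 0.00763), or -1.80 with trends on gene length and GC content removed. LRP1, a receptor that clears amyloid, rose by 1.27 ± 0.25 (adjusted p = 0.0022), but changed by -0.18 with trends on gene length and GC content removed (adjusted p = 0.69; alternatives 4.53e-06 to 0.69). The list's median was 0.36 and its mean 0.24, while its camera test pointed down (adjusted p = 0.919), and its median was -0.14 with those trends removed.

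Outside the lists, the largest rises among genes with every PCNSV library above the normal median included EBLN2, a bornavirus-derived gene, at 6.20 ± 1.04 (adjusted p = 0.000549), and ALDH8A1, an aldehyde dehydrogenase, at 7.24 ± 1.16 (adjusted p = 0.000344). They also held MKRN3, a ring finger protein, at 6.72, a 105-fold rise (adjusted p = 0.000884). Without normal replicate 3 the changes of EBLN2 and MKRN3 were 8.04 and 8.53, and ALDH8A1 kept 2 normal counts, a ratio of 466 scaled by depth with a 95% counting interval of 129 to 3847. DPEP2, a dipeptidase of leukocytes, had no count in normal brain and was at least 39.8-fold higher, or 133-fold against the floor without normal replicate 2 (adjusted p = 0.00016). Among the largest falls, MAN1A2 (ENSG00000198162, chromosome 1, 117367449 to 117528872), a mannosidase of the Golgi, averaged 291 ± 125 CPM (SD, n = 13) against 2548 ± 1525 (SD, n = 4), a log2 fold change of -3.13 ± 0.36 (SE; adjusted p = 3.13e-05). ATP6V1G2 (ENSG00000213760, chromosome 6, 31544462 to 31548427), a neuronal subunit of the vesicular proton pump, averaged 64.8 ± 43.9 CPM against 669 ± 291, a change of -3.37 ± 0.62 (adjusted p = 0.00129). SLIRP, a mitochondrial RNA-binding protein, changed by -3.13 ± 0.56 (adjusted p = 0.000968), MT1X, a metallothionein, by -3.08 ± 0.56 (adjusted p = 0.00101), and NDUFB1, a complex I subunit, by -3.04 ± 0.44 (adjusted p = 0.000144). The log2 fold changes ran, over the alternatives, from 5.78 to 8.04 for EBLN2, 6.27 to 8.53 for MKRN3, -3.64 to -2.39 for SLIRP, -3.94 to -2.74 for MT1X and -3.66 to -2.62 for NDUFB1. Lower genes were shorter than higher ones (median length 4647 against 7514 bases) and had a lower GC content (42.7% against 51.8%), among genes with a mean log2 CPM of at least 4.

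Across all 40 lists, camera with a preset correlation of 0.01 called 15 higher and 7 lower in PCNSV, and none of these calls held with an estimated correlation. Besides the lists described with their camera values, it called the monocyte and macrophage (adjusted p = 0.0182), co-stimulation (0.0253), excitatory neuron (0.0169) and synaptic (0.00224) lists. It further called the interferon gamma (0.0303), complement (0.0304), astrocyte (0.0303), CD8 and NK (0.0329), MHC class I (0.0363) and immediate early (0.0363) lists. Each of these 10 lists had adjusted p = 0.614 with an estimated correlation. The number of higher lists was 4 with the excitatory neuron level as covariate, 5 without the 3 libraries lowest in synaptic genes, and 9 without GV replicate 6 or without normal replicate 3. With that covariate the only higher lists left were T cell, plasma cell, class II and toll-like receptor genes. It ended the calls of monocyte (0.177), microglia (0.059), dendritic (0.126), type I interferon (0.217), interferon gamma (0.259), complement (0.217) and co-stimulation genes (0.18). Those of CD8 and NK (0.217), class I (0.343), immediate early (0.18), excitatory (0.387), synaptic (0.379) and astrocyte genes (0.211) ended too. Without the 3 low-synaptic libraries the calls of monocyte (0.107), microglia (0.0779), dendritic (0.0945), type I interferon (0.192), interferon gamma (0.196), complement (0.147) and co-stimulation genes (0.163) ended. So did those of CD8 and NK (0.147), class I (0.192), immediate early (0.147), excitatory (0.147) and astrocyte genes (0.149). Among genes with a mean log2 CPM of at least 4, the T cell, CD8 and NK, dendritic and co-stimulation lists were not tested. Each had fewer than 4 members left there. Calls of monocyte (0.0561), microglia (0.0849), type I interferon (0.193), interferon gamma (0.163) and complement genes (0.0542) ended there. Those of immediate early (0.0561), excitatory (0.171), synaptic (0.0648) and astrocyte genes (0.248) ended as well. Removing trends on length and GC content ended those of class I (0.13), complement (0.0625) and immediate early genes (0.0616), and genes at thinned depth as covariate those of monocyte (0.078), excitatory (0.05003) and astrocyte genes (0.138). The replicate number as a block compared AB libraries alone with normal brain. It ended the calls of T cell (0.0956), microglia (0.122), dendritic (0.162), type I interferon (0.349), interferon gamma (0.68), co-stimulation (0.482) and immediate early genes (0.284). It also ended CD8 and NK and class I (0.996 each), excitatory (0.263), synaptic (0.0859) and astrocyte genes (0.154). The astrocyte call ended without the 3 shallow libraries (0.0848), the dendritic call under the stricter filter (0.0513) and the class I call with the total count as covariate (0.0594). Without GV replicate 6 the calls of interferon gamma, complement and astrocyte genes (0.0534 each), of CD8 and NK genes (0.0553) and of class I and immediate early genes (0.056 each) ended. Without normal replicate 3 those of interferon gamma (0.0517), CD8 and NK (0.0715), class I (0.0694) and immediate early genes (0.0667) ended. Without normal replicate 1 those of complement and class I (0.119 each) and CD8 and NK genes (0.063) ended, and without normal replicate 2 that of astrocyte genes (0.0782). Without GV replicate 5 the class I (0.0634) and immediate early (0.065) calls ended, and without GV replicate 7 the class I call (0.0546). Without LV replicate 9 the CD8 and NK (0.0539) and immediate early (0.0547) calls ended, and without LV replicate 11 the CD8 and NK (0.0577) and class I (0.0548) calls. The exact permutation of list levels called 9 lists higher and 4 lower, each described above. It called 0 and 0 without normal replicate 1, 2 or 3, 20 higher without AB replicate 4, 18 higher without LV replicate 9, and 4 higher and 3 lower without the 3 libraries lowest in synaptic genes. With 1 normal library left out, 560 splits remain of 2380.

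The comparisons among the codes ask whether the groups named AB, GV and LV differ, a question the titles pose without saying what the codes are. T cell genes were highest in GV, at a level of 3.23 ± 1.01 (SD, n = 4), against -1.32 ± 1.73 in AB (SD, n = 4) and 0.40 in LV (from -2.70 to 3.86, n = 5). GV libraries also had the highest MHC class II level, 6.28 ± 1.55, against 4.17 ± 1.02 in AB and 4.66 ± 1.60 in LV. Plasma cell genes were highest in LV, at 3.37 ± 1.68, against 0.52 ± 2.45 in AB and 1.61 ± 2.34 in GV. Synaptic genes had a level of 7.05 ± 0.44 in AB, 4.36 ± 2.94 in GV and 6.03 ± 2.37 in LV, where GV replicates 5 and 6 and LV replicate 11 stood at 2.23, 1.48 and 1.86 and the other GV and LV libraries at 6.31 to 7.57. The T cell level of these 3 libraries was 3.17, 4.42 and 3.86. None of these differences passed correction in the exact permutation of list levels, which has too few splits at these group sizes to decide. Camera with a preset correlation called those of T cell (adjusted p = 1.03e-14), class II (2.03e-09) and synaptic genes (6.38e-11) between AB and GV and of plasma cell genes between AB and LV (8.31e-08). These had adjusted p = 0.129, 0.159, 0.221 and 0.2 with an estimated correlation. The exact permutation p of the T cell level between AB and GV was 0.0286 over 70 splits, which is the smallest that 4 against 4 allow, and its adjusted p was 0.254.

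No gene was called by edgeR between AB and GV, AB and LV, GV and LV, or in a test of any difference among the codes, where 939, 506, 615 and 637 genes had an unadjusted p under 0.05. DESeq2 called 39, 33, 17 and 1 genes and limma-voom 3, 2, 4 and 9. Without GV replicate 8, edgeR called 27 genes between AB and GV, 27 between GV and LV and 7 in the overall test. Differences at these group sizes were simulated in 25 genes per size and direction, all with a mean log2 CPM over 2. The share called of 16-fold differences was 72% to 80% between AB and GV and 84% to 92% between AB and LV. Between GV and LV it was 76% to 88%. For 4-fold differences these shares were 16% to 24%, 28% to 48% and 24% to 32%. Camera with the preset correlation called 26, 25 and 29 lists between AB and GV, AB and LV, and GV and LV, and 14 rather than 25 without LV replicate 11. With an estimated correlation it called none (smallest adjusted p = 0.129, 0.155 and 0.226). Exact permutations of list levels called none (smallest adjusted p = 0.254, 0.886 and 0.447), an outcome that these group sizes nearly fix. The sizes allow 70 splits between AB and GV, and 126 between AB and LV and between GV and LV. With so few splits, a list at the smallest possible p passes adjustment only if many others are at or near it. More of them are needed between AB and GV than in the other comparisons. These permutations therefore cannot tell whether list levels differ among the codes. EGR2 averaged 172 ± 164 CPM in GV (SD, n = 4), 20.4 ± 20.2 in AB (SD, n = 4) and 24.1 ± 27 in LV (SD, n = 5), differences that were not called.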

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

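The tests of length and GC content, of detected genes as covariate, of depth and myelin, and of red cell, endothelial and mural genes were chosen after the results were seen, as were the neuron level as covariate and the rise in the number of splits from 60 to 100.

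The lists of ribosomal protein, nuclear-encoded respiratory chain and heat shock genes were lower in PCNSV by permutation of list levels, but not by camera with an estimated correlation. Of their genes 12 of 22, 12 of 21 and 5 of 12 were called lower, and 1 heat shock gene was called higher. The median log2 fold change of the 55 members was -0.87 relative to genes with a mean log2 CPM of at least 4. Removing each library's trend on gene length and GC content left -0.88, a covariate for the number of genes detected at equal depth left -0.91, and the excitatory neuron level as covariate left -0.80, so these values argue against each of these as the whole cause. The excitatory level is an imperfect measure of neurons. GV replicate 7 stood at -0.05 in it, but at 6.31 in synaptic and 7.14 in cerebellar neuron genes. A first test of the neuron level, a pooled correlation over the 13 PCNSV libraries, was set aside after it was seen because those levels form 2 clusters. Within the 9 libraries of the higher cluster the level of the 3 lists and the neuron level had Pearson r = 0.42 (exact permutation p = 0.229) and Spearman rho = 0.63 (exact permutation p = 0.076). A difference between the groups in preservation or time to fixation may also lower these transcripts, and no label allows a test. MALAT1 was higher in PCNSV, at 2.66% to 11.5% of counts, against 1.06% to 2.37% in normal brain. Whether it goes with the level of these lists within a group was not tested.

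GV replicates 5 and 6 and LV replicate 11 held synaptic levels of 1.48 to 2.23. The shallowest library had a synaptic level of 6.48, so low depth does not account for them. All 3 lay above every other library in myelin genes, the lowest at 7.56, so more myelinated tissue in those biopsies may contribute. Their astrocyte level was lower (5.15 to 5.85, against 6.76 to 7.86 in the other PCNSV libraries), and their T cell level was 3.17 to 4.42 and their MHC class II level 6.50 to 7.80. Loss of neurons in the tissue stays open as well, since the labels give no region or pathology, and no biological explanation was tested.

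Leukocyte genes rose, with a median log2 fold change of 2.93 over 91 members when the 30 with no normal count (33%) stand at their bound. The highest of 10000 random lists matched on PCNSV level reached 1.22, and at most 17.6% of their members lacked a normal count, so fewer detected genes in normal libraries do not account for the rise. The leukocyte level rose by 4.74 more than the red cell level (exact permutation p = 0.0151) and by 3.16 more than the endothelial and mural level (exact permutation p = 0.00084), which argues against blood in the biopsies and against a lower share of neural cells as the whole cause. Infiltrating leukocytes may be the source, a hypothesis that these counts alone cannot separate from other differences between the sets of biopsies.

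Of 100 splits, drawn from 2380 possible, only the real one called as many as its 3775 genes between PCNSV and normal brain. The highest of the others gave 3, which argues against chance for this number. The splits cannot tell the diagnosis from a difference in handling that goes with the normal libraries. Chance was not excluded for the number of lists called in that comparison, where 29 of 100 splits gave as many as the real 22 and the highest of the others gave 32. Between the codes, chance was not excluded for the number of lists: 16 of 35 splits gave as many as the real 26 between AB and GV (highest other 31), 6 of 100 as many as the real 25 between AB and LV (highest other 27), and 6 of 100 as many as the real 29 between GV and LV (highest other 32). For the number of genes the real value was 0, which every split reaches (35, 100, 100 and 100 splits for AB with GV, AB with LV, GV with LV and any difference), so the splits say nothing about chance there. The highest of the others were 1, 1, 916 and 122. A split with 916 genes points to a structure of the samples other than the codes. It puts GV replicates 5, 6 and 7 and LV replicate 11 together. The excitatory neuron levels of these 4 libraries were -2.46 to -0.05, against 3.50 to 5.20 in the other 9 PCNSV libraries. GV replicates 5 and 6 and LV replicate 11 were the highest in myelin genes, and GV replicate 7 in cerebellar neuron genes.

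Of 277 groups of 4 or 5 libraries screened for a library far from the others, 30 held one, against 13.9 that chance gives at about 1 in 20 groups. The 30 include genes with counts in only 1 normal library, which the rule always flags, so the excess is overstated. Among list levels, as mean log2 CPM, AB replicate 4 stood apart in inhibitory neuron genes at 0.45, and LV replicate 9 in endothelial genes at 1.42 and hypoxia genes at 1.24. LV replicate 11 stood apart in excitatory neuron genes at -1.14, inhibitory neuron genes at -2.20 and synaptic genes at 1.86. Among the normal libraries, replicate 3 stood apart in T cell genes at -2.59. Normal replicate 2 did so in inhibitory neuron genes at -0.26 and type I interferon genes at -0.35, and normal replicate 4 in interferon gamma genes at 1.43 and cytokines at 0.00277. LV replicate 9 and normal replicate 2, both shallow, showed 13601 and 12412 genes at 2.5 M counts.

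Single genes also set 1 normal library apart from the other 3, in CPM. For EGR2, UBASH3A, CHIT1, CYP21A2, POU2AF1, IL12RB1, PRF1, HSPA6 and FAT2 the other 3 held no count. The rule flags such a library whatever the size of its count, so these flags carry no weight. UBASH3A, CHIT1 and POU2AF1 each rest on 1 normal count. In normal replicate 1 these were EGR2 at 0.049, GBP5 at 0.306, UBASH3A at 0.0123 and CHIT1 at 0.0123. In normal replicate 2 they were HMGN5 at 324, FLT1 at 602, COL3A1 at 33.9, GJA1 at 693 and HBB at 6434. In normal replicate 3 they were CYP21A2 at 0.931 and POU2AF1 at 0.00941. In normal replicate 4 they were IL12RB1 at 0.291, FRRS1 at 0.315, PRF1 at 0.267, C3 at 521, HSPA6 at 0.0485 and FAT2 at 1.55.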

How the results depend on the processing

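The trend removal, the covariates for detected genes and neuron level, the fits without low-synaptic or shallow libraries, the limit on log2 CPM and the permutations of list levels were chosen after the data were seen. Between PCNSV and normal brain 2130 genes were higher and 1645 lower. Relative log expression scaling gave 2488 and 1334 and moved the median of all genes from 0.33 to 0.48 on the log2 scale. Upper-quartile scaling gave 2276 and 1474, no filter 1545 and 1681, the stricter filter 2034 and 1642, the total count as covariate 2499 and 1632, and the 4-group fit 1717 and 1641. Without the 3 shallow libraries the counts were 2112 and 1759, and without the 3 low-synaptic libraries 1945 and 1593. The counts moved by more than 1.5 times with the replicate number as a block (352 and 291), DESeq2 (4607 higher, with 548 genes given no adjusted p), limma-voom (2831 lower), trends on length and GC content removed (2619 lower), genes at thinned depth as covariate (1349 higher) and genes with a mean log2 CPM of at least 4 (1399 higher, where fewer genes were tested). Leaving out 1 library gave 1029 to 2524 higher and 903 to 1941 lower. For the numbers of genes called among the codes, DESeq2 gave 39, 33, 17 and 1 and limma-voom 3, 2, 4 and 9 (AB with GV, AB with LV, GV with LV, any difference), while leaving out 1 library gave 0 to 27, 0, 0 to 27 and 0 to 7. The lists called by camera, 15 higher and 7 lower, became 0 and 0 with an estimated correlation, and 0, 0 and 0 between the codes. They became 6 and 4 with the replicate block, 4 higher with the neuron level as covariate and 5 higher without the low-synaptic libraries. With a mean log2 CPM of at least 4 they became 4 and 4. Under that limit the T cell, CD8 and NK, dendritic and co-stimulation lists were too short to be tested. By permutation of list levels the numbers were 9 and 4. Leaving out 1 library gave 9 to 18 higher and 6 to 9 lower, and among the codes 20 to 31, 14 to 25 and 23 to 30. The permutation of list levels gave 0 to 20 higher and 0 to 4 lower with 1 library left out, and 4 higher without the low-synaptic libraries. LRP1 reversed, to -0.18, with the trends removed. Apart from the gaps that fewer genes or samples leave, the cause was not tested. Over all named genes and alternatives, 4923 results kept their side of the threshold, 134 passed it newly, 592 no longer passed and 1 reversed. For the lists these numbers were 1102, 47, 120 and 0. A change of sign counted as a reversal only where a call was involved. Uncalled genes changed sign as well, such as FAT2, from 8.33 to -1.64 at the lowest. The floor for genes absent from normal brain depends on depth: 3 counts are 0.0237 CPM in the deepest normal library and 0.428 in the shallowest.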

Other observations

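GV replicate 7 stood above the other PCNSV libraries in cerebellar neuron genes. Its level of these genes was 7.14, against at most 1.99 in the other 12 PCNSV libraries and 1.42 in normal brain. FAT2, a cadherin of cerebellar granule cells, reached 1753 CPM in it, and at most 2.04 in the others. The labels give no brain region for any library.

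Gene classes held the following calls between PCNSV and normal brain, where 18.2% of all tested genes were called, and no enrichment of a class was tested. Of 43 joining segments of T cell receptors 21 were higher and 0 lower, while 0 of 11 variable segments of T cell receptors were called. Of 41 variable segments of immunoglobulins 8 were higher and 0 lower. Among 536 antisense RNAs 99 were higher and 4 lower, among 298 long intergenic noncoding RNAs 45 and 7, and among 367 small nucleolar RNAs 17 and 54. These classes are named as the deposited table gives them, and how strands were counted is not stated.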
